A study of Streptomyces natalensis with 6 samples.

How the data were processed

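RNA was measured in Streptomyces natalensis HW-2, a filamentous soil bacterium that makes the antifungal polyene natamycin (also called pimaricin). The valine arm received 0.5% L-valine at 36 h, the control arm received none, and broth was taken at 48, 60 and 72 h. Ribosomal RNA was removed, libraries were made with a marked cDNA strand and sequenced on an Illumina HiSeq instrument, per the labels' protocols. There were 6 libraries, 1 for each treatment and time. Whether they came from separate flasks is not stated, so every p-value given here measures only the spread between these samples.

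The deposited table lists a read count and an FPKM value per library for each of 7809 genes, per the file headers, with the gene's ID, its product text and its position on 1 of 63 contigs. Reads were aligned with Bowtie2, per the submitters' processing notes. The version of that program, the counting program, the genome build and the annotation version are not given in the sources used here. The deposited counts were whole numbers with no scaling between libraries. The FPKM values of the authors equalled the count divided by the gene's span in kilobases and by the library's total, put on the FPKM scale, for 100% of values, within 0.006, and were not used in the tests. Gene spans were multiples of 3 for 97.2% of genes, so those of protein genes were taken as coding lengths. Whether counting used the strand is not stated, so reads of overlapping or facing genes, and of close copies such as the GroEL genes, could have been shared between them. Total counts per library ran from 9161546 to 11452340. No genome sequence was used here, and gene names and positions are those of the deposited table.

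The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr, which left 7779 genes. Libraries were scaled with TMM factors. A quasi-likelihood model with time and valine as additive terms was fitted to all 6 libraries, with 2 residual degrees of freedom, a common biological coefficient of variation of 0.230 and 8.40 prior degrees of freedom. It gave the difference between valine and control shared by the 3 times, and the changes from 48 h to 60 h and to 72 h shared by both arms. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors given with ± are approximate standard errors. Each is the absolute fitted log2 fold change divided by the square root of its quasi-likelihood F statistic.

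Each time alone has 1 library per group and thus no replicates and no p-value. For these comparisons the log2 ratio of TMM-scaled counts scaled to a common library total (CPM) was taken, with a prior count of 2, and genes beyond 2-fold were counted. Its 95% interval is an exact (Clopper-Pearson) binomial interval of the pair of counts, and it covers counting error only. The ratios of the 3 times were compared by correlation across genes, which are not independent replicates. The range of each correlation came from 500 bootstrap resamples of contigs. It covers the choice of genes and leaves out the noise of single libraries, which all genes share.

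Gene lists, 23 in number, were matched on product text. They were tested with limma 3.58.1 on log2 CPM: camera, which sets a list against all other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation, and fry, which asks whether a list's genes move, on balance, one way and compares it with no other genes. Both were adjusted over the lists. For each time, a list's median ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 10 bins, as a percentile. The random lists were drawn gene by gene, whereas neighbouring or related genes can move together. An extreme percentile is thus a description and not a test. The lists were used exactly as fixed, with some part-word matches, such as an enzyme of tRNA modification counted under ATP synthase. The ribosomal and transfer RNA, phage and mobile element, and heat-shock lists were included as signs of sample quality. They stand for ribosomal RNA removal, other DNA and RNA, or the state of the culture. Whether their values reflect these or a response was not tested. No gene was named after natamycin or pimaricin. By the rule set for that case, the natamycin cluster was taken as the run of neighbouring genes from the first to the last type I polyketide synthase gene within 40 genes of an oxidase gene. No gene was named cholesterol oxidase, so a GMC family oxidoreductase, the family of that enzyme, was used in its place, a choice made after the product texts were seen. The run is called the presumed natamycin run here.

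The tests, the lists, the rule for naming genes and most alternatives were chosen before the data were examined. Genes were named among those with a product other than hypothetical and a mean of at least 10 CPM: for valine across times, 10 in each direction, past the test or, where too few passed, of the same sign at all 3 times and ranked by their smallest ratio; for each time, the 4 with the largest and the 4 with the smallest ratio; for each list, up to 4 with the largest mean ratio and all genes of the natamycin run; and for 72 h against 48 h, the 5 with the largest change in each direction. Chosen after values were seen were the groups of neighbouring or related genes, other single genes named beside the rule's genes, the list tests of 72 h against 48 h, scaling by total counts in the gene tests, leaving out single libraries, the count of ratios whose interval lay wholly beyond 2-fold, and lists trimmed of part-word matches. Among the trimmed lists, the natamycin run was instead widened by flanking genes, to 19 genes. The alternatives chosen beforehand were DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma-trend, no filter, a mean of at least 50 CPM, a prior count of 0.5, removal of ribosomal and transfer RNA genes, no time term, and leaving out each time.

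The tests were run first on simulated counts with known changes, drawn from the means and sizes of these libraries. For valine against control, over 7774 genes, 68.7% of genes changed 2-fold and 100% of those changed 4-fold or 8-fold were called, and 6.28% of calls were false. Genes were drawn independently there, with the same valine change at every time. These rates may thus not carry over to the real libraries, where the valine ratios differed between times. For 60 h against 48 h, over 7776 genes, 32.8% of 2-fold, 98.5% of 4-fold and 100% of 8-fold changes were called, and 13.5% of calls were false. For 72 h against 48 h, over 7772 genes, 26.9% of 2-fold and 100% of 4-fold and 8-fold changes were called, and 8.48% of calls were false. Of 200 genes made higher at 48 h and lower at 60 h, the test across times called 0, while 196 lay beyond 2-fold higher at 48 h and 195 beyond 2-fold lower at 60 h.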

Results

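Transcript levels of 7809 genes were measured by RNA sequencing in Streptomyces natalensis HW-2, a producer of the antifungal natamycin, to learn how its gene expression differed at successive times after valine was added. The 6 libraries were control and valine at 48, 60 and 72 h. Total counts were 9349946 and 11452340 in control and valine at 48 h, 11000237 and 9161546 at 60 h, and 9277261 and 10175646 at 72 h. The chaperones and proteases of the heat-shock response, such as GroEL and DnaK, which fold or degrade proteins under heat stress, took 3.90% of counts in the control library at 48 h and 2.64% in its valine partner, against 0.831% to 1.47% in the 4 libraries of the later times. The presumed natamycin run took 3.03% and 3.22% of counts at 48 h in control and valine, 2.08% and 1.91% at 60 h, and 1.49% and 1.80% at 72 h. Ribosomal and transfer RNA genes took 0.0502% in the control library at 48 h and 0.115% in the valine library, which stood at the low and high ends of the 6 libraries. The 48 h libraries also stood apart from each other, with a root mean square log2 difference of 0.580, against 0.415 between the arms at 60 h and 0.315 at 72 h.

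Among named genes whose ratio had the same sign at all 3 times, the lowest fitted values belonged to a pair of neighbouring genes on contig NZ_JRKI01000034. SNA_RS25990 (from 294192 to 295100), annotated as 4-hydroxy-tetrahydrodipicolinate synthase, an enzyme of lysine synthesis, was lower with valine at every time, with log2 ratios of -0.81 at 48 h, -2.55 at 60 h and -1.26 at 72 h. Its neighbour SNA_RS25995, a methyltransferase, had ratios of -0.83, -2.29 and -1.09. On the positive side, SNA_RS13805, an MbtH family protein of the kind that assists peptide synthetases, had 2.56, 0.42 and 1.23, and SNA_RS13795 near it, the 2,3-diaminopropionate synthesis protein SbnB, had 1.42, 0.64 and 0.40. A run of 3 neighbours was also higher throughout: phosphoenolpyruvate synthase SNA_RS21280 had ratios of 0.42, 1.69 and 0.43, the ATP-grasp protein SNA_RS21285 had 0.52, 1.62 and 0.54, and the transporter SNA_RS21275 had 0.47, 1.35 and 0.37. Inositol-3-phosphate synthase SNA_RS02250, which makes the precursor of inositol lipids and mycothiol, had 0.51, 0.36 and 1.01, and the PadR family regulator SNA_RS02245 beside it had 0.64, 0.39 and 0.83.

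The other named genes also had ratios of constant sign. On the positive side these were the MoaD/ThiS family protein SNA_RS35705 (1.33, 0.28 and 0.55), the leucine-rich repeat protein SNA_RS15705 (1.03, 0.38 and 0.39) and the DinB family protein SNA_RS00530 (0.64, 0.36 and 0.52). On the negative side, the TfuA-like protein SNA_RS24240 had -2.16, -0.41 and -0.32, inositol monophosphatase SNA_RS27305 had -0.90, -0.43 and -0.32, and the zinc transporter protein SNA_RS07010 had -0.45, -0.33 and -0.29. The other 5 lower genes, an N-acetyltransferase, glycine amidinotransferase, DNA polymerase I, a monooxygenase and a methyltransferase, were expressed at low levels, and each had an interval at 48 h, 60 h or 72 h that reached 0.

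No gene passed the test of valine across the 3 times in edgeR's quasi-likelihood fit. At an unadjusted p under 0.05 there were 66 genes, where chance gives 389, and limma-trend called 0 with 67 at that level. The error of this fit holds any difference of the valine effect between times as well as library noise. The ratios at 48 h and 60 h ran opposite to each other (r -0.441), which widens that error. These counts therefore do not show a lack of response at single times. DESeq2's Wald test called 1 gene, SNA_RS25990, at a log2 fold change of -1.51 and an adjusted p of 0.0459, with 69 genes at the unadjusted level. With libraries scaled by total counts, edgeR called 2 genes, SNA_RS25990 (adjusted p 0.0015) and SNA_RS25995 (adjusted p 0.00341). Without the 48 h libraries it called 12 genes, 4 higher and 8 lower, and without only the control or only the valine library of 48 h it called 10 and 9. These 12 held both neighbours again, at -1.91 (adjusted p 0.000138) for SNA_RS25990 and -1.69 (adjusted p 2.55e-05) for SNA_RS25995. They also held 2 subunits of the Kdp potassium pump, SNA_RS38935 at -1.48 (adjusted p 4.04e-05) and SNA_RS30085 at -1.05 (adjusted p 0.0215), the tRNA-Pro gene SNA_RS00185 at -1.84 (adjusted p 0.0096), and hypothetical proteins SNA_RS15450, SNA_RS25850 and SNA_RS40860 on the lower side. On the higher side were succinate dehydrogenase SNA_RS09440 at 1.26 (adjusted p 0.0198), argininosuccinate synthase SNA_RS12570 at 1.23 (adjusted p 0.0399), the small subunit of acetolactate synthase SNA_RS31695 at 1.09 (adjusted p 0.0331), and the hypothetical protein SNA_RS13920. Genes of these alternatives were named after their values were seen. The fit without the 48 h libraries had fewer residual degrees of freedom than the full fit. Leaving out 1 library of 48 h acts like leaving out both, so those calls are not separate support. Of the 12 genes, only both neighbours and SNA_RS09440 (0.0011) had the sign of their call at 48 h too. The Kdp genes SNA_RS38935 and SNA_RS30085 stood at 2.58 and 2.37 there. SNA_RS13920 had -0.21 at 72 h, and tRNA-Pro had a mean of 1.8 CPM.

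At 48 h, 12 h after the addition, genes for phenylacetate and proline use had some of the lowest ratios and potassium uptake genes some of the highest, in groups picked after the ratios were seen. The 6 genes for phenylacetate degradation between SNA_RS02555 and SNA_RS02595 had a median log2 ratio of -2.19, with PaaN (SNA_RS02595) at -2.53 (interval -2.58 to -2.48). Next to it, 3 genes of a 2-oxo acid dehydrogenase complex (SNA_RS02615 to SNA_RS02625), which oxidises branched-chain keto acids or pyruvate, had a median of -2.51, with SNA_RS02615 at -2.67 and SNA_RS02620 at -2.51. A run of 8 genes for proline use (SNA_RS25910 to SNA_RS25945) had a median of -2.12, and 6 genes around a glutamine synthetase (SNA_RS11350 to SNA_RS11375) had -1.69. The ATP-binding protein SNA_RS04505 stood at -2.63. On the other side were 5 genes grouped under the Kdp potassium pump, an uptake system used under potassium shortage or osmotic stress. Their median was 2.37, with KdpA (SNA_RS30095) at 2.39 and subunit F (SNA_RS38935) at 2.58. An ABC transporter run of 4 genes (SNA_RS29560 to SNA_RS29575) had a median of 2.41, and the peroxide detoxifying protein SNA_RS17690 stood at 2.60 (interval 2.49 to 2.71). The MbtH gene SNA_RS13805 and tRNA-Met SNA_RS07325 (2.61) were the other 2 of the highest 4 named genes.

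Beyond 2-fold at 48 h were 594 of 7779 genes, 391 higher and 203 lower with valine. With total-count scaling the split was 235 higher and 354 lower, because the median ratio of all genes moved from -0.06 to -0.22. The interval lay wholly beyond 2-fold for 355 genes, 235 higher and 120 lower. The largest ratios of any gene belonged to the neighbouring hypothetical proteins SNA_RS22210 (4.31) and SNA_RS22215 (3.64), which stood at -3.20 and -2.84 at 60 h.

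At 60 h, most genes for making and breaking down branched-chain amino acids had positive ratios, as did those of a succinate dehydrogenase. Of the 12 genes for synthesis of valine, leucine and isoleucine, 11 had positive ratios and 5 lay beyond 2-fold, among them 2-isopropylmalate synthase SNA_RS06945 at 1.73 and the acetolactate synthase subunits SNA_RS31695 at 1.62 and SNA_RS31700 at 1.61. The methylmalonyl-CoA mutase gene SNA_RS32205, whose enzyme links propionate and valine breakdown to the tricarboxylic acid cycle, stood at 2.22 (interval 2.11 to 2.33). The 3 genes of a succinate dehydrogenase (SNA_RS09430 to SNA_RS09440) had a median of 1.80. A chlorinating enzyme, SNA_RS13325, stood at 2.65 after -1.96 at 48 h, the VCBS repeat protein SNA_RS38285 at 2.67 after -1.64, and the aquaporin SNA_RS11580 at 2.10. The lowest named genes were SNA_RS25990, SNA_RS25995, the serine protease SNA_RS36200 at -2.01 and the response regulator SNA_RS36195 beside it at -1.67. Beyond 2-fold were 190 genes, 67 higher and 123 lower, against 111 higher and 51 lower with total counts, where the median of all genes moved from 0.01 to 0.19. The interval lay wholly beyond 2-fold for 97 genes, 41 higher and 56 lower.

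At 72 h, a run of polysaccharide genes and the chaplins, picked after the ratios were seen, had positive ratios, and the Kdp genes negative ones. All 24 genes of a polysaccharide synthesis run on contig NZ_JRKI01000029 (SNA_RS20830 to SNA_RS20945, from 212976 to 246561) had positive ratios, with a median of 1.07 after -0.11 at 48 h and 0.08 at 60 h. With total-count scaling 23 of the 24 were positive. Its phosphoesterase SNA_RS20830 stood at 2.02, the sugar transferase SNA_RS20845 at 1.87 and glucose-1-phosphate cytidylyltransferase SNA_RS20905 at 1.86. The chaplins, hydrophobic proteins that coat aerial filaments, had positive ratios in 9 of 9 genes, or in 7 with total counts, with SNA_RS11895 at 1.76. Their median was 0.62 at 72 h, after -0.03 at 48 h and -0.74 at 60 h, where 0 of 9 were positive. The Kdp genes stood at a median of -1.57, with subunit F (SNA_RS38935) at -2.13, KdpA (SNA_RS30095) at -1.76 and KdpC (SNA_RS30085) at -1.57, and the short-chain dehydrogenase SNA_RS18640 at -1.82. Beyond 2-fold were 110 genes, 67 higher and 43 lower, against 51 higher and 56 lower with total counts, where the median of all genes moved from 0.02 to -0.11. The interval lay wholly beyond 2-fold for 55 genes, 41 higher and 14 lower. All per-time comparisons rest on 1 library per group, with no replicate check. The directions of genes and lists are those under TMM scaling, which does not set the median of all genes to 0. Those of small ratios depend on the scaling.

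**Figure D1:**
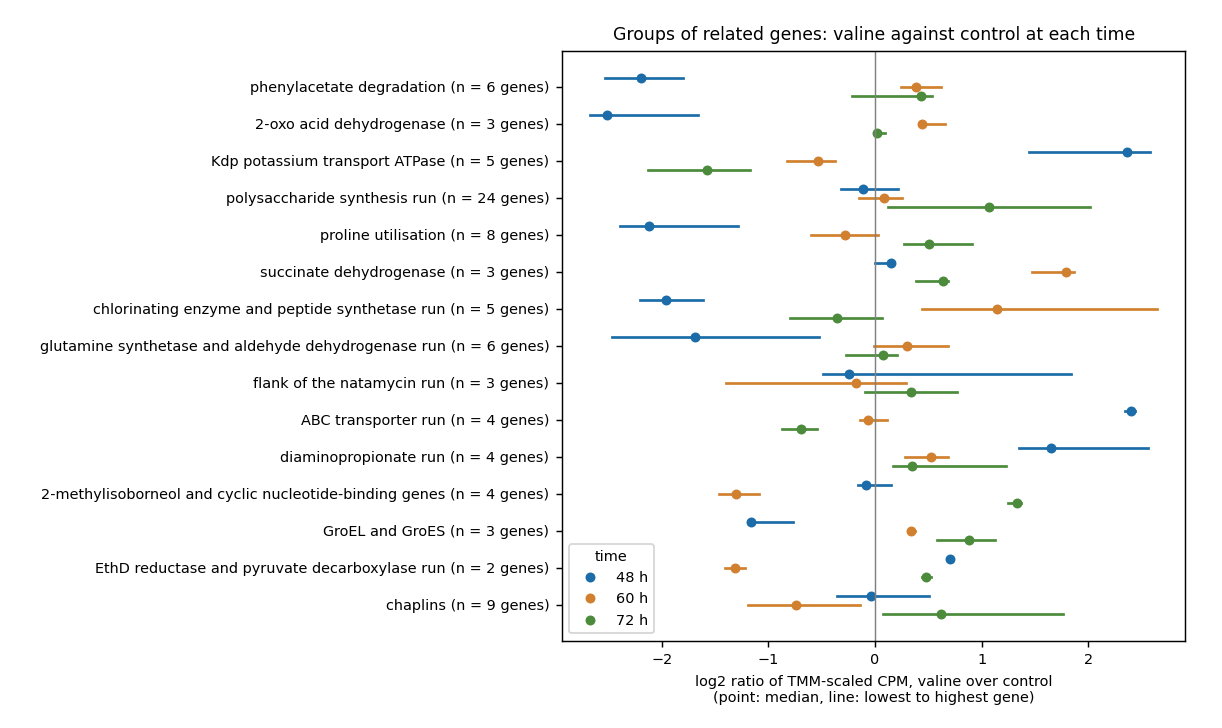
Log2 ratio of valine over control at each time (x axis, TMM-scaled CPM) for groups of related genes, with the median as a point and the lowest to highest gene as a line. The genes grouped under the Kdp potassium pump lay at a median of 2.37 at 48 h and -1.57 at 72 h, and the phenylacetate genes at -2.19 and 0.43.

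The presumed natamycin run, 14 genes from SNA_RS21320 to SNA_RS21385 on contig NZ_JRKI01000029 (from 346322 to 423594), holds polyketide synthases and tailoring, sugar and export genes. Its median log2 ratio was 0.22 at 48 h, -0.45 at 60 h and 0.49 at 72 h, and 0.05, -0.27 and 0.36 with total counts. At 60 h, 0 of the 14 genes had positive ratios, and at 72 h all 14 did. Against random lists of like expression, the 72 h median lay at percentile 99.97, the 60 h median at 2.56 and the 48 h median at 31.7. Those lists were drawn gene by gene, whereas the run is a single stretch of neighbours that can move together. These percentiles are therefore a description and not a measure of chance. At 72 h the largest ratio was 1.17, for GDP-mannose 4,6 dehydratase SNA_RS21340, an enzyme of sugar synthesis, followed by thioesterase SNA_RS21335 at 0.60, the ABC transporter genes SNA_RS21345 at 0.56 and SNA_RS21350 at 0.52, the aminotransferase SNA_RS21360 at 0.54 and cytochrome P450 SNA_RS21365 at 0.53. The polyketide synthases SNA_RS21320, SNA_RS21325, SNA_RS21330, SNA_RS21375 and SNA_RS21385 had 72 h ratios of 0.48, 0.44, 0.18, 0.44 and 0.42, and -0.42, -0.31, -0.17, -0.27 and -0.14 at 60 h. The oxidoreductase SNA_RS21355, ferredoxin SNA_RS21370 and the phosphatase SNA_RS21380 had 0.49, 0.47 and 0.22 at 72 h. Just outside the run, the LuxR family regulator SNA_RS21305 stood at 1.84 at 48 h and -1.40 at 60 h, while the median of the 3 flanking genes was -0.25 and -0.17 at these times. No gene of the run was called for valine in edgeR, over all genes or adjusted over the list alone, and the run's list test gave an adjusted p of 0.114 in camera and 0.852 with an estimated correlation. Widened by flanking genes to 19 genes, the run gave an adjusted p of 0.209 in camera. The test of the 14 genes depended on the times used. The run passed as higher without the 60 h libraries (adjusted p 5.92e-05, and 0.604 with an estimated correlation), and it pointed lower without either or both of the 72 h libraries (0.457 without both).

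**Figure D2:**
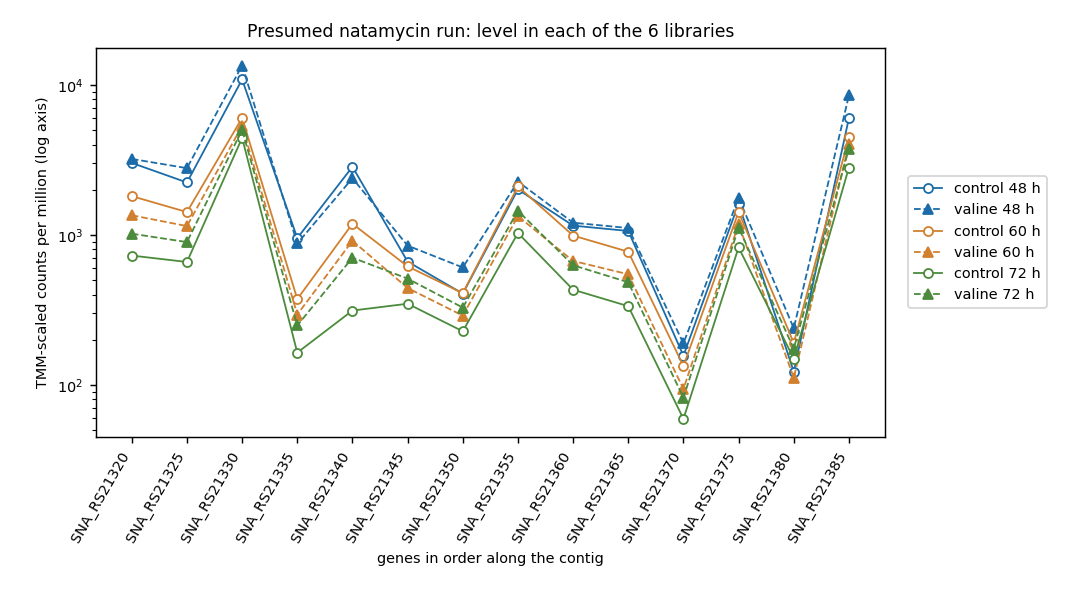
Level of each gene of the presumed natamycin run in each of the 6 libraries (y axis, TMM-scaled CPM on a log axis; x axis, genes in order along the contig). The median log2 ratio of valine over control was -0.45 at 60 h and 0.49 at 72 h.

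Among the other gene lists, branched-chain amino acid synthesis had the widest range of medians over the times. Its medians were -0.49 at 48 h, 0.61 at 60 h and 0.28 at 72 h, at percentiles 0.01, 100 and 98.8. The 9 degradation genes had medians of -0.09, 0.73 and -0.06, with 6 of 9 positive at 60 h, and methylcrotonoyl-CoA carboxylase SNA_RS05930 at 1.13. The 6 transport genes had -0.15, 0.29 and -0.08. Fatty acid beta-oxidation genes had -0.43, 0.37 and -0.07, with 54 of 60 positive at 60 h and 8 of 60 at 48 h. For acetyl-CoA and malonyl-CoA supply the medians were -0.21, 0.30 and -0.08, for non-ribosomal peptide synthetases and siderophores -0.15, 0.36 and -0.04, and for modular polyketide synthases, mostly those of the natamycin run, 0.22, -0.22 and 0.44.

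Among energy and translation genes, those of ATP synthase stood at -0.46, 0.19 and 0.15, NADH dehydrogenase and cytochrome oxidases at 0.25, -0.28 and 0.20, the tricarboxylic acid cycle at 0.10, 0.11 and 0.07, and glycolysis at 0.16, -0.14 and 0.12. Ribosomal proteins stood at 0.01, 0.17 and 0.26, with 61 of 68 positive at 72 h, and translation factors and tRNA synthetases at 0.40, -0.15 and 0.10, with valine--tRNA ligase SNA_RS06550 at 0.98 at 48 h. Nitrogen assimilation genes had -0.37, 0.03 and -0.18, with the ammonium transporter SNA_RS31295 at -1.29, the PII regulator SNA_RS31290 at -1.03 and glutamine synthetase SNA_RS11360 at -1.90 at 48 h. Phosphate limitation genes had -0.12, -0.33 and 0.14, and the phosphate regulator PhoU (SNA_RS35910) stood at -1.52 at 48 h.

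Sporulation and aerial development genes had medians of 0.29, -0.43 and 0.11, with the cell division regulator SNA_RS12720 of the SsgA family at 1.49, -1.35 and 0.81. Sigma and anti-sigma factors had 0.24, -0.24 and 0.09, with the SigE family factor SNA_RS34255 at 2.06 at 48 h. Heat-shock chaperones and proteases had 0.17, -0.08 and 0.24. Within that list ClpB (SNA_RS03315) stood at 1.27 and DnaK (SNA_RS03280) at 0.94 at 48 h, while the GroEL genes SNA_RS35695 and SNA_RS37595 stood at -1.16 and -1.17. Oxidative stress genes had -0.02, -0.21 and 0.12, secreted hydrolases -0.24, 0.06 and 0.09, phage and mobile elements -0.08, -0.15 and -0.01, and ribosomal and transfer RNA genes 0.42, -0.35 and -0.29. With total counts the sign of the median turned for translation factors, glycolysis, heat-shock genes and phage elements at 60 h, for ribosomal proteins, the tricarboxylic acid cycle and glycolysis at 48 h, and for translation factors, the tricarboxylic acid cycle, glycolysis, sporulation, oxidative stress, sigma factors and secreted hydrolases at 72 h.

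**Figure D3:**
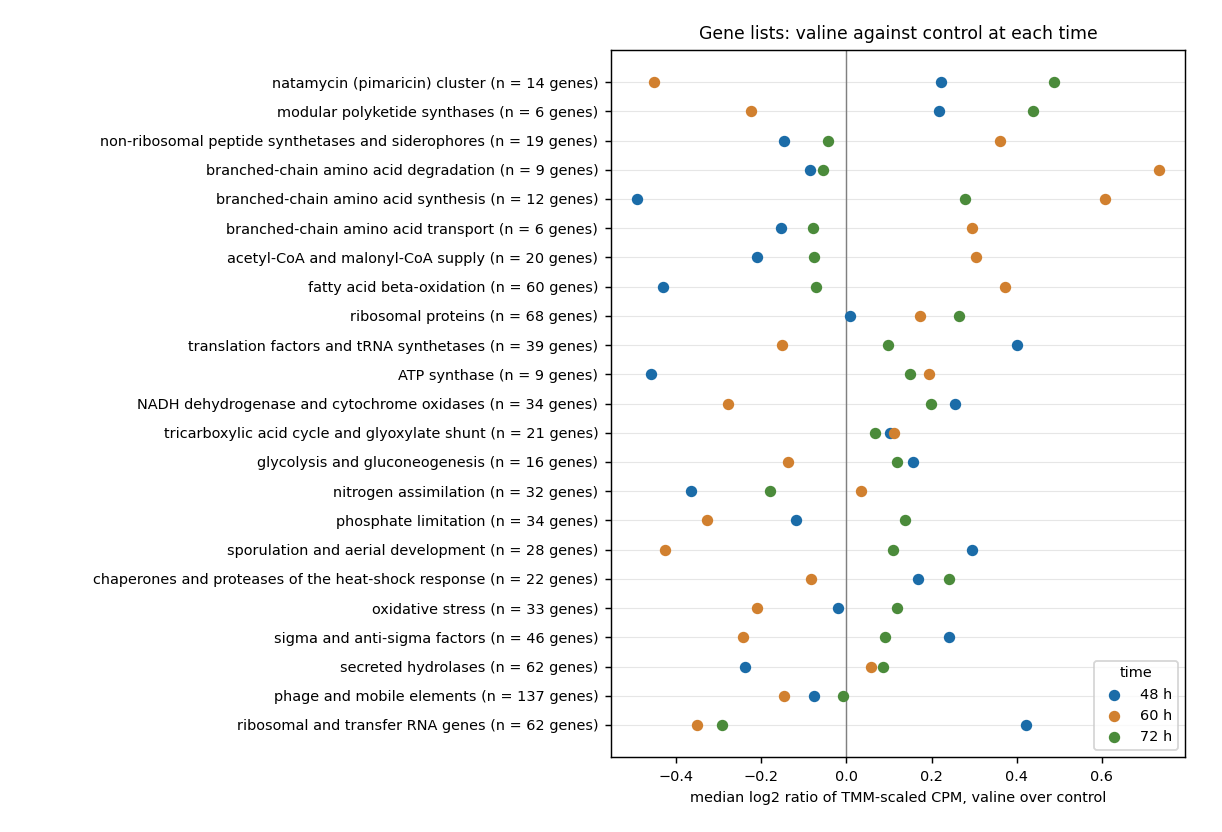
Median log2 ratio of valine over control (x axis, TMM-scaled CPM) of each of the 23 gene lists at 48, 60 and 72 h. The synthesis genes of branched-chain amino acids lay at -0.49 at 48 h and 0.61 at 60 h.

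Across the 3 times, 5 of the 23 lists passed camera with its preset correlation. Ribosomal proteins (adjusted p 2.28e-07), translation factors and tRNA synthetases (0.00113) and NADH dehydrogenase and cytochrome oxidases (0.00344) were higher with valine, and nitrogen assimilation (0.000729) and phage and mobile elements (0.000927) were lower. None held with an estimated correlation, where the adjusted p was 0.638 for phage elements and 0.852 for the other 4. None passed fry, with an adjusted p of 0.938. Camera does not match genes on expression. Among random lists of like expression, ribosomal proteins lay at percentiles 0.18, 100 and 99.99 at the 3 times, so they stood low at 48 h. NADH dehydrogenase lay at 80.2, 1.8 and 98.6, and translation factors at 93.3, 66.2 and 30.6. Nitrogen assimilation lay at 0.01, 59.3 and 0, and phage elements at 89.4, 0.02 and 63.25. The other 18 lists, the natamycin run among them, had adjusted p in camera from 0.0865, for branched-chain amino acid synthesis, the tricarboxylic acid cycle and heat-shock genes, to 0.820, for acetyl-CoA and malonyl-CoA supply. Of these, phosphate limitation (0.287) passed as lower when trimmed of part-word matches (adjusted p 0.0121, and 0.810 with an estimated correlation). The fitted median and the direction of the test differed in sign for that supply list (-0.03, higher) and for branched-chain amino acid transport (0.01, lower). No gene of any list was called for valine in edgeR, also adjusted over the list alone. Calls of single lists depended on the times used. Without the 48 h libraries, or without only the control or only the valine library of 48 h, translation factors pointed lower (adjusted p 0.956), and the NADH dehydrogenase (0.454) and nitrogen (0.162) calls were lost. Without either or both of the 60 h libraries the phage call was lost (0.194 without both), and without either or both of the 72 h libraries only the call of translation factors was kept (0.0387 without both), with 0.0800 for ribosomal proteins, 0.0687 for NADH dehydrogenase and 0.0502 for nitrogen and phage genes. Other lists passed when a time was left out, with the preset correlation only. None did with an estimated correlation, where the smallest adjusted p was 0.696 without 48 h, 0.604 without 60 h and 0.994 without 72 h. That correlation was estimated from 2 residual degrees of freedom, and from fewer with a time left out. A list that failed with it is therefore not shown to be unchanged. Leaving out 1 library of a time acts like leaving out both, since the remaining library sets that time's level alone. Without 48 h, branched-chain amino acid synthesis (3.67e-15) and degradation (0.000412), beta-oxidation (0.00108) and acetyl-CoA and malonyl-CoA supply (0.0125) passed as higher and ribosomal and transfer RNA genes (2.44e-18) as lower. Without 60 h, the natamycin run, modular polyketide synthases (0.0147), sporulation (0.00124), sigma factors (0.0180) and heat-shock genes (0.0242) passed as higher and beta-oxidation (5.92e-05) as lower. Without 72 h, degradation of branched-chain amino acids and ribosomal and transfer RNA genes passed as higher and phosphate limitation as lower, each at 0.0387. The calls of ribosomal and transfer RNA, phage and heat-shock genes may reflect sample quality, for which these lists were included.

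The valine ratios of different times were compared across the 7779 genes to see whether the response kept its direction. Ratios at 48 h and 60 h ran opposite to each other, with a Pearson r of -0.441 (bootstrap range -0.480 to -0.401) and a Spearman rho of -0.502. Those of 60 h and 72 h had r of -0.230 (-0.274 to -0.197) and rho of -0.306, and those of 48 h and 72 h had r of 0.034 (-0.021 to 0.073) and rho of 0.133. Only 867 genes, 11.1%, had the same sign at all 3 times, where independent signs would give 25%. Of the genes beyond 2-fold at both 48 h and 60 h, 52 had opposite signs, the chlorinating enzyme and the VCBS repeat gene among them, and 6 had the same sign.

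**Figure D4:**
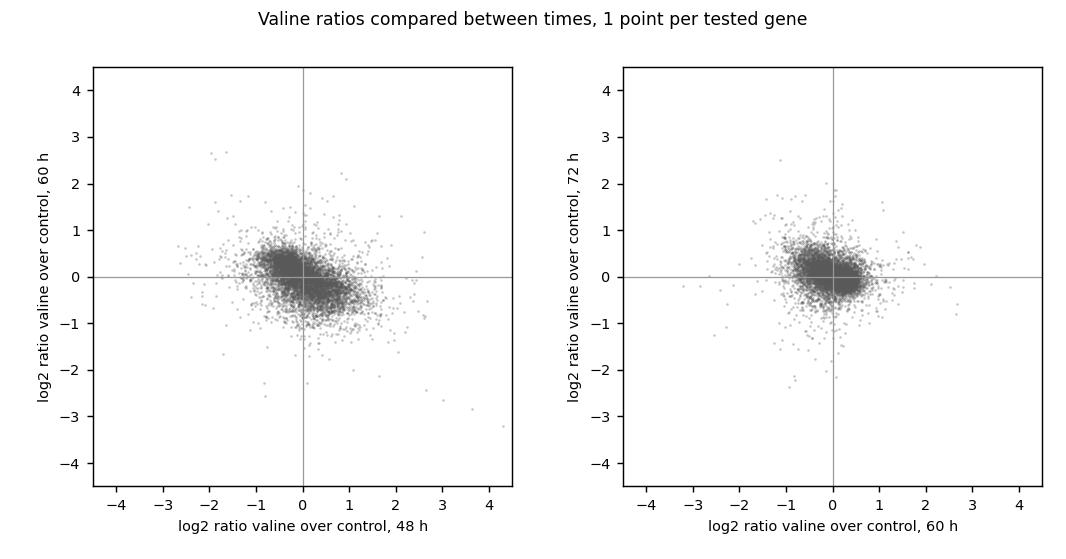
Log2 ratio of valine over control of each of 7779 genes at 60 h against 48 h (left) and at 72 h against 60 h (right), 1 point per gene. Pearson r was -0.441 on the left and -0.230 on the right.

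From 48 h to 60 h, in the fit shared by both arms, 3 genes fell. The cold-shock protein SNA_RS03665, an RNA chaperone, changed by -2.56 ± 0.33 on the log2 scale (adjusted p 0.0458). The neighbours deoxyribose-phosphate aldolase SNA_RS34230, an enzyme of nucleoside breakdown, and betaine-aldehyde dehydrogenase SNA_RS34235 changed by -2.72 ± 0.36 (adjusted p 0.0458) and -2.65 ± 0.29 (adjusted p 0.0186). These are edgeR values from 2 libraries per time, with 918 genes at an unadjusted p under 0.05, and limma-trend also called 3. The count was 1 with DESeq2 size factors and 221 with DESeq2's Wald test (50 higher, 171 lower), and 204 (122 higher, 82 lower) with total counts, where the median of all genes moved from 0.00 to 0.22. It was 269 and 559 without the control and the valine library of 48 h, 0 without either library of 60 h, 76 without either library of 72 h, 73 without both of these, and 1 without the ribosomal and transfer RNA genes.

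From 48 h to 72 h, in the fit shared by both arms, part of the ribosomal protein genes and most ATP synthase genes fell. Of 68 ribosomal protein genes, 31 fell and 2 rose (41 and 6 adjusted over the list alone), with a median log2 change of -1.25. L7/L12 (SNA_RS37270) changed by -2.46 ± 0.42 (adjusted p 0.0170) and L9 (SNA_RS02200) by -1.96 (adjusted p 0.0167), while an L31 gene of low expression (SNA_RS19655) rose by 2.75 (adjusted p 0.0269). Of 9 genes listed under ATP synthase, 7 fell (8 over the list alone), with subunit beta (SNA_RS32300) at -2.39 (adjusted p 0.0170). Of 22 heat-shock genes, 8 fell (10 over the list alone), among them GroEL SNA_RS35695 by -3.48 ± 0.70 (adjusted p 0.0261), GroEL SNA_RS37595 by -2.83 (adjusted p 0.0279) and DnaK SNA_RS03280 by -2.14 (adjusted p 0.0381). In glycolysis 2 of 16 genes fell (8 over the list alone), with pyruvate kinase SNA_RS32155 at -1.90 (adjusted p 0.0248) and glucose-6-phosphate isomerase SNA_RS10330 at -1.85 (adjusted p 0.0275).

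In the presumed natamycin run, 3 of 14 genes fell from 48 h to 72 h (7 over the list alone) and the median change was -1.22. They were GDP-mannose 4,6 dehydratase SNA_RS21340 at -2.40 (adjusted p 0.0324), thioesterase SNA_RS21335 at -2.15 (adjusted p 0.0187) and ferredoxin SNA_RS21370 at -1.29 (adjusted p 0.0362). Branched-chain amino acid synthesis had a median of -1.02, with 0 genes called over all genes and 6 over the list alone. In sporulation and aerial development the median was 0.40, with 1 gene lower over all genes, the WhiB family regulator SNA_RS33025 (-2.11, adjusted p 0.0128), and 2 higher over the list alone. Translation factors had 4 genes lower (8 over the list alone), NADH dehydrogenase and cytochrome oxidases 2 (8), oxidative stress 3 (3), the tricarboxylic acid cycle 1 (1), phosphate limitation 0 (3) and modular polyketide synthases 0 (2). Phage and mobile elements had 2 higher (0 over the list alone).

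Among genes with a named product and a mean of at least 10 CPM, the largest declines were those of the VCBS repeat protein SNA_RS38285 at -4.06 ± 0.82 (adjusted p 0.0269), the chlorinating enzyme SNA_RS13325 at -3.67 ± 0.84 (adjusted p 0.0402), the ABC transporter SNA_RS05045 at -3.53 ± 0.44 (adjusted p 0.0126), GroEL SNA_RS35695, and the cold-shock protein SNA_RS03665 at -3.32 ± 0.34 (adjusted p 0.00657). The genes of that kind that rose most were the EthD family reductase SNA_RS20595 at 3.07 ± 0.46 (adjusted p 0.0139) and its neighbour pyruvate decarboxylase SNA_RS20590, which makes acetaldehyde from pyruvate, at 2.26 ± 0.43 (adjusted p 0.0213). They were followed by the response regulator SNA_RS36195 at 1.94 ± 0.44 (adjusted p 0.0384), the DUF485 protein SNA_RS30300 at 1.66 ± 0.37 (adjusted p 0.0357) and the LacI family regulator SNA_RS02025 at 1.58 ± 0.29 (adjusted p 0.0197).

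In all, edgeR called 309 genes between 72 h and 48 h, 31 higher and 278 lower, and DESeq2's Wald test 669 (77 higher, 592 lower). With total counts the calls were 812, of which 541 were higher and 271 lower, and the median of all genes moved from 0.06 to 0.46. The directions above are those under TMM scaling, and the balance of higher and lower calls depends on the scaling. The count also depended on single libraries: it was 946 and 823 without the control and the valine library of 48 h, 282 and 0 without the control and the valine library of 60 h, 13 without both libraries of 60 h, and 86 and 102 without the control and the valine library of 72 h. All 309 genes kept their sign in each of these alternatives. Without both libraries of 60 h, 6 of the 13 calls were higher and 7 lower.

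Of the 23 lists, 17 passed camera for 72 h against 48 h with its preset correlation, a test added after the data were seen. Ribosomal proteins (adjusted p 4.46e-18), the natamycin run (2.21e-10), ATP synthase (6.21e-10), translation factors (2.01e-09) and heat-shock genes (1.33e-08) were lower. So were NADH dehydrogenase and cytochrome oxidases (4.09e-06), glycolysis (9.14e-06), the tricarboxylic acid cycle (8.85e-05), oxidative stress (0.000113), modular polyketide synthases (0.000384), branched-chain amino acid synthesis (0.00199), phosphate limitation (0.00772) and acetyl-CoA and malonyl-CoA supply (0.0241). Phage and mobile elements (7.85e-10), ribosomal and transfer RNA genes (0.000722), sporulation (0.00306) and sigma factors (0.0330) were higher. The phage, ribosomal and transfer RNA, and heat-shock lists were included as signs of sample quality, which their calls may reflect. None held with an estimated correlation, where the smallest adjusted p was 0.235, for phage elements, and it was 0.406 for the natamycin run and 0.279 for ribosomal proteins. That correlation too was estimated from 2 residual degrees of freedom, so these lists are not shown to be unchanged. The supply list lost its call when trimmed of part-word matches (adjusted p 0.0640), and the medians of NADH dehydrogenase (-0.34), phosphate limitation (-0.34), the supply list (-0.27) and branched-chain amino acid degradation (-0.26) were positive with total counts. Beta-oxidation had a median of 0.03, below the median of all genes (0.06), and its test, which sets a list against all other genes, pointed lower. The other 6 lists did not pass: degradation of branched-chain amino acids (0.223), their transport (0.728), beta-oxidation (0.728), nitrogen assimilation (0.728), secreted hydrolases (0.424) and non-ribosomal peptide synthetases (0.530).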

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

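Of the tests reported here, those of exchanged libraries, of a valine culture ahead of its control by the change from 48 h to 60 h, of a valine culture behind its control at 60 h, of the library scaling and of calls among less expressed genes were chosen after the result was seen. The differences between times listed below were not tested, since each time has 1 library per group. Except for the correlation, each list stood out because its median ratio lay below percentile 2.5 of random lists at some time and above percentile 97.5 at another, with opposite signs. These percentiles treat the genes of a list as independent and are a description only.

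The valine ratios at 48 h and 60 h were negatively correlated across genes, at r = -0.4406. Suppose the control and valine libraries of 48 h alone had been exchanged. With a response alike at all times, the ratios of 60 h and 72 h would still go together. Their correlation was -0.230, below 0 by more than its bootstrap range of -0.274 to -0.197. That argues against such an exchange only under this condition and as far as the genes drawn are concerned. The bootstrap ranges given here leave out the noise of single libraries, which all genes share. If the response changed direction between times, an exchange at 48 h stays open. An exchange at 60 h stays open even with a response alike at all times, since the 48 h and 72 h ratios had r of 0.034 (-0.021 to 0.073). For a valine culture ahead of its control at 48 h, the test set beforehand took the change from 60 h to 72 h. The 48 h ratio should have correlated with it positively. It had r of -0.105 (-0.19 to -0.037) and rho of -0.259 (-0.311 to -0.217), which went against that explanation by the rule set. After this was seen the rule was set aside, since a culture ahead at 48 h need not have entered that change. With the change from 48 h to 60 h, the 48 h ratio had r of 0.059 (-0.005 to 0.112) and rho of -0.042, which decides nothing. The explanation was therefore left open. A culture behind at 60 h also stays open, with r of -0.186 but a Spearman rho of -0.02 (-0.054 to 0.013) between the 60 h ratio and the change from 48 h to 72 h. So do a response to valine that changed direction between times and differences between single flasks, which were not tested.

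The medians of several lists had opposite signs at different times. For branched-chain amino acid synthesis the median at 60 h minus that at 48 h was 1.10, and at 72 h minus 48 h it was 0.77. Fatty acid beta-oxidation had 0.80 from 48 h to 60 h and -0.44 from 60 h to 72 h. ATP synthase had 0.65 from 48 h to 60 h, and NADH dehydrogenase and cytochrome oxidases had 0.48 from 60 h to 72 h. Sporulation and aerial development had -0.72 and sigma and anti-sigma factors had -0.48 from 48 h to 60 h. Ribosomal and transfer RNA genes had -0.77 from 48 h to 60 h and -0.72 from 48 h to 72 h, in a list included as a sign of ribosomal RNA removal.

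Genes called between 72 h and 48 h leaned lower, at 278 of 309 calls in the fit of all 6 libraries. The lean depended on the libraries used. Without both libraries of 60 h, 6 calls were higher and 7 lower. With single libraries left out, the share of lower calls was smaller for some and larger for others. More power for abundant genes, which lean lower, was argued against as the cause among less expressed genes, under TMM scaling in that fit of all libraries. Of 114 calls in the 3 lower expression groups, where most genes were higher by any size, 85.1% (bootstrap range 73.5% to 95.7%) were lower. From the least expressed group up, the calls were 12 lower and 8 higher, 37 and 4, and 48 and 5, so the lean was weakest in the least expressed. This share was not taken with total counts or with libraries left out, and its range leaves out the noise of single libraries. Among the 1556 most expressed genes it stays open, since 69.2% of them were lower by any size, so that the 97.4% of lower calls after drawing their counts down to 4.11% (200 lower calls before and 149 after in a fit of these genes alone, against 122 in the fit of all genes) may follow from that lean. Scaling of the libraries also stays open: with total counts 33.4% of calls were lower, but a shift of the median of all genes from 0.06 to 0.46 could turn that share by itself. A change of gene expression with culture age was not tested apart from these.

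For valine across the 3 times, the real split of the 6 libraries called 0 genes. The highest of the other splits also called 0, so 10 of 10 splits gave as many. At an unadjusted p under 0.05 the real split had 66 genes, the lowest count. Exchanging the arms at 60 h gave 1217, at 48 h 527 and at 72 h 179, and the highest of the other splits gave 1421. Exchanged libraries and a response that changed direction between times could both give such counts, so these do not tell them apart. With 10 splits a share under 0.05 cannot be reached.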

How the results depend on the processing

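Chosen after the data were seen were total counts in the gene tests, leaving out single libraries, the counting interval, trimmed lists, an estimated correlation with a time left out and all list tests of 72 h against 48 h. Fitting valine without the time term, the block that pairs the arms, called 0 genes with 22 at an unadjusted p under 0.05, and DESeq2 size factors, limma-trend, no filter and removal of ribosomal and transfer RNA genes also left the valine count at 0. For valine the count became 1 with DESeq2's Wald test, 2 with total counts, 12 without the 48 h libraries and 0 to 10 without single libraries. For 60 h against 48 h it became 1 with DESeq2 size factors or without ribosomal and transfer RNA genes, 221 with the Wald test, 204 with total counts, 73 without the 72 h libraries and 0 to 559 without single libraries. For 72 h against 48 h it became 669 with the Wald test, 812 with total counts, 13 without the 60 h libraries and 0 to 946 without single libraries. The size factors (264), limma-trend (330), no filter (313) and removal of RNA genes (306) kept that count within 1.5 times. Fewer libraries mean fewer residual degrees of freedom, and the remaining library of a time sets that time's level alone and is assumed to vary like the others; otherwise the cause was not tested. Genes beyond 2-fold numbered 362 at 48 h, 120 at 60 h and 60 at 72 h at a mean of at least 50 CPM, which tests fewer genes, and 355, 97 and 55 where the counting interval had to lie beyond 2-fold, while the other 4 settings kept each count within 1.5 times. The valine list tests called 0 lists with an estimated correlation, also with any time left out, and 10 without the 60 h libraries, and 4 to 10 without single libraries. Translation factors pointed lower without the 48 h libraries (adjusted p 0.9557, and 0.9876 with an estimated correlation), and without control (0.9555) or valine (0.9553) of that time. Leaving out single libraries gave it adjusted p from 0.0003509 to 0.9555. Beta-oxidation, which pointed lower, passed as higher without the 48 h libraries (0.001081), without control (0.001077) or without valine (0.001074) of that time. Leaving out times or single libraries gave it adjusted p from 5.918e-05 to 0.7844. Ribosomal and transfer RNA genes, which pointed lower, passed as higher without the 72 h libraries (0.0387), without control (0.03888) or without valine (0.03889) of that time. Leaving out times or single libraries gave it adjusted p from 2.439e-18 to 0.8659. The list tests of 72 h against 48 h called 0 with an estimated correlation and 16 or 17 otherwise. The correlation of the 60 h and 72 h ratios became -0.334 at a mean of at least 50 CPM, and the cause was not tested; those of the other times moved by less than their bootstrap error. Of the named genes' ratios at their own time, 14 of 24 moved beyond their counting interval with total counts and 0 with a prior count of 0.5. Of the 10 named changes from 48 h to 72 h, 4 lost their call without the 60 h libraries, and all 10 kept it with total counts. Depth limits low-expressed genes most: at 48 h the interval of tRNA-Met SNA_RS07325, at a mean of 15.4 CPM, ran from 2.11 to 3.29, and that of GroEL SNA_RS35695, at 4753 CPM, from -1.18 to -1.15.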

Other observations

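Groups of related genes outside the fixed lists, all noticed in the values and not tested, also had like ratios. The gene of 2-methylisoborneol synthase (SNA_RS10100), which makes an earthy odorant, its methyltransferase SNA_RS10095 and the cyclic nucleotide-binding proteins SNA_RS14190 and SNA_RS14195 on another contig had a median log2 ratio of -0.09 at 48 h, -1.30 at 60 h and 1.33 at 72 h. The 4 genes of the diaminopropionate run, which also holds an L-asparagine oxygenase, were higher with valine at each time, at medians of 1.65, 0.53 and 0.35. The run of the chlorinating enzyme with an acyl carrier protein, a thioesterase and a peptide synthetase had medians of -1.96, 1.14 and -0.36, and 3 of its 5 genes fell from 48 h to 72 h in edgeR. GroEL and GroES had -1.16, 0.34 and 0.88, unlike ClpB and DnaK of the same list, which were above 0 at 48 h.

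Among hypothetical proteins, SNA_RS18610 stood at 3.01 at 48 h and -2.65 at 60 h, SNA_RS25860 at 2.66 and -2.43, and SNA_RS01760 at 2.51 at 72 h. In a principal component analysis of all tested genes, the first component (50.4% of variance) set the 48 h libraries apart from the others, and the next (25.4%) set the control and valine libraries of 48 h at opposite ends, at 23.9 and -23.9. By root mean square difference the control library of 48 h was nearer to the valine library of 60 h (0.506) than to its own valine partner (0.580) or to the control library of 60 h (0.696). The control library of 60 h was nearest to the valine library of 72 h (0.386).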
